A study of Cupriavidus metallidurans CH34 with 16 samples.

How the data were processed

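The series holds 16 scanner files from single-colour Agilent arrays of Cupriavidus metallidurans, 1 per sample, and 1 value table. Per the labels, cells were grown in mineral salts medium with 0.2% sodium gluconate to a turbidity of 100 Klett units, total RNA was purified on columns with DNase treatment, checked by PCR for residual DNA and checked for integrity, and was labelled with Cy3. Per the file headers, the intensity values of the scanner files were extracted from the scans with Feature Extraction 10.7.3.1; they are raw intensities on a linear scale, with the mean, the local background and the detection columns of the extraction software deposited beside them. The value table, as deposited, holds 9734 features in 16 columns, and its scale is not given in the sources used here. Among features above a low cut of signal, 98.6% to 98.7% of its values lay within 1% of a scaled scanner signal. That signal was the mean minus the mean local background, averaged over the probes of a feature and divided by a constant per array. Over all features the correlation with that signal was 0.9993 to 1.0000 on untreated arrays but only 0.6801 to 0.8753 on treated ones. Its column medians were 0.107, 0.1 and 0.102 for untreated AE104, 0.249, 0.25 and 0.281 for AE104 with zinc, 0.248, 0.238 and 0.267 for AE104 with EDTA, 0.107, 0.113 and 0.114 for CH34, 0.197 and 0.229 for the deletion strain with zinc, and 0.212 and 0.238 for it with EDTA. All 16 columns had a mean of 1.027, so they shared a mean but not a median. The scaling is not described in the sources used here, so the value table served only as an alternative.

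Each array carried 15207 probes that were not controls and 536 control spots. Of the probes, 9843 were for genes and 5364 for intergenic stretches, giving 6681 gene features and 3419 intergenic features; 3162 gene features had 2 probes. Gene features bore either a symbol or a locus tag, and no file pairs the tags with names. A gene was taken to belong to the plasmids when its probe number came before that of dnaA. Locus tags of that block ran from 5942 to 6344, leaving aside longer tags such as Rmet_62630. Intergenic features were placed by the plasmid in their name. No spot was saturated and 0 to 31 spots per array were marked as outliers, which were left out. The negative controls minus local background were 35.9 to 45 on arrays of the first scan day and 3.49 to 4.86 on those of the second. Slide and scan day were read from the file headers: AE104 with zinc, untreated AE104 and CH34 had a slide each, and AE104 with EDTA shared 1 with both groups of the deletion strain. Untreated arrays were scanned on another day than treated ones. Median SDs of replicates on the log2 scale were 0.17 in CH34, 0.14 in untreated AE104, 0.32 in AE104 with zinc, 0.18 in AE104 with EDTA, 0.21 in the deletion strain with zinc and 0.16 in it with EDTA.

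The processed signal of the extraction software, which is corrected for background, was taken on the log2 scale, each array was centred on its 75th percentile over the probes that are not controls, and the probes of a feature were averaged. The 5695 gene features with a probe well above background on every array of at least 1 group entered the fit. Only features measured in a comparison were counted as changed, those with a probe well above background on every array of at least 1 of its groups. All 6 groups were fitted in limma 3.58.1 with 1 mean per group, and moderated statistics came from the empirical Bayes step, with 4.87 prior degrees of freedom. The prior variance followed a trend over mean level. P-values were adjusted by the Benjamini-Hochberg method over all features in the fit, within a comparison. A feature was called changed at an adjusted p under 0.05 and a log2 change of at least 1 in size. The interaction was the EDTA-over-zinc change of the deletion strain minus that of AE104. A fold against a group not well above background on each of its arrays was printed only as an at-least fold, the mean of the bright group over the mean, in the dim group, of the higher of the lowest well-above-background signal on the array and the probe's own signal.

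Genes were named by a rule written beforehand: per comparison the 10 called genes with the largest rise and the 10 with the largest fall whose arrays do not overlap between groups, with 5 per plasmid and 10 each way outside the plasmids for CH34 and 5 each way for the interaction. To these came up to 4 called members of each gene list, or up to 2 with the smallest p where none was called, and the genes zupT, zur, zntA, cadA and dmeF where measured. The rule was also applied among features with a symbol, a step added once the symbols were known and before their values were seen. Gene features were not assigned to single plasmids, so the 10 largest changes each way over the whole plasmid block replaced the 5 per plasmid. The text leaves out some genes so chosen. Of the last 5 genes only zupT is reported, through the tag entered for it; the files name none of the others, which are not analysed here.

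Of 32 gene lists written before the files were opened, 7 had at least 3 features by symbol, and 25 could not be resolved without a table of tags and names. A further 8 lists were added after the symbols and before the values were seen, and with the plasmid block 16 were tested. Lists were tested by camera with the preset correlation of 0.01, adjusted over lists within a comparison, and again with a correlation estimated per list. The first run counted changes and tested lists over all features kept for the fit, as designed, and gave 44 list calls. Some of those rested on features below background in both groups, so counts and list tests were then restricted to measured features; that switch came after the first result was seen, and the first form was kept as an alternative. Runs of neighbouring tags were compared with the longest run in 1000 shuffled orders.

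The steps were tested on simulated data made with the real group sizes, with 5695 features of which 200 changed per comparison. The noise was normal, with 1 SD per feature pooled over all groups. The larger spread of AE104 with zinc (median SD 0.32) was not copied, so the simulation does not describe comparisons with that group. At a log2 change of 1.5, between 69.0% (interaction) and 89.0% (EDTA against zinc) were recovered, and at 3 between 92.0% and 100.0%; 1 to 9 unchanged features were called per comparison. Sample numbers within groups were checked for pairing across groups: in 36 pairs of same-numbered arrays the correlation of residuals ran from -0.24 to 0.13 with a median of -0.01, so no block was used. The mapping of labels to files was checked through the plasmid block and the deleted gene.

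Alternatives were centring on the median, quantile normalization, normexp background correction (offset 50) with quantile normalization, no filter, a stricter filter, only the groups of a comparison in the fit, other thresholds, a replicate block, the value table, and the omission of each array in turn. Values of the value table under 0.01 were set to 0.01 before the log2 scale was taken. Added after results were seen were a common floor at a log2 level of -2.39 and the counting of all features kept for the fit. A block for slide could not be run in 6 comparisons, where slides follow the groups. Scan day follows the groups in the 2 comparisons of treated with untreated AE104 and is the same for all arrays in the others, so no block for it was run. The 2 comparisons within 1 slide were also fitted on the arrays of that slide alone. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.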

Results

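Transcript levels of Cupriavidus metallidurans, a soil bacterium known for its resistance to heavy metals, were measured on 16 single-colour Agilent arrays, 1 per RNA sample. Strain CH34 carries the plasmids pMOL28 and pMOL30, and AE104 is its plasmid-free derivative. In the deletion strain, per the labels, the zupT gene had been removed from AE104; zupT encodes a metal cation importer of the ZIP family. Untreated AE104, AE104 grown with 10 µM ZnCl2, AE104 grown with 50 µM EDTA and untreated CH34 had 3 arrays each, and the deletion strain had 2 arrays with zinc and 2 with EDTA. EDTA is a chelator that binds zinc and other divalent metal cations. The arrays carried 9843 gene probes for 6681 gene features, of which 329 bore a gene symbol and 6352 only a locus tag that the files do not pair with a name. Between 51.1% and 82.7% of all probes were well above background on an array. AE104_zinc replicate 3 stood apart, with 56.2% of control spots above background against 33.2% to 38.1% on the other arrays, and with 49.2% of plasmid probes above background against 7.6% and 7.8% on the other zinc arrays of AE104. Pairwise correlations across features between replicate arrays lay between 0.981 and 0.992 in 5 groups and between 0.916 and 0.985 in AE104 with zinc. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, and the 2 or 3 arrays per group limit the precision of every change given. That spread was pooled over all 6 groups. Replicates of AE104 with zinc varied most, with a median SD of 0.32 on the log2 scale against 0.14 to 0.21 in the other groups. P-values of comparisons with AE104 with zinc rest in part on the less variable groups and may be too small.

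The deleted gene was examined before the comparisons, since its signal checks the labels. Rmet_2621 had been entered for zupT before the data were examined; the files do not pair the tag with a name. It was well above background on all 12 arrays of CH34 and AE104 and on 0 of the 4 arrays of the deletion strain. Other features were also above background on all treated AE104 arrays and on 0 arrays of the deletion strain. Among them was Rmet_4645, at least 12.2-fold lower with zinc and at least 32.3-fold lower with EDTA, so such a loss was not particular to Rmet_2621. Its mean log2 level, relative to the 75th percentile of each array, was -1.15 ± 0.30 (SD, n = 3) in AE104 with zinc and -5.66 ± 0.22 (SD, n = 2) in the deletion strain with zinc. With EDTA the levels were -0.71 ± 0.22 (SD, n = 3) and -4.98 ± 0.27 (SD, n = 2). The deletion strain was at least 5.19-fold lower with zinc (log2 change -4.51, SE 0.24, adjusted p = 3.95e-08) and at least 4.39-fold lower with EDTA (log2 change -4.28, SE 0.24, adjusted p = 8.4e-08). Normexp background correction with quantile normalization gave -0.94 with zinc, short of the fold minimum, and -1.07 with EDTA. The authors' value table gave -1.71 and -1.52. The neighbouring Rmet_2622 had mean levels of -0.23 ± 0.14 and -0.27 ± 0.12 in AE104 with zinc and EDTA (SD, n = 3 each) and of 1.58 ± 0.04 and 1.74 ± 0.03 in the deletion strain (SD, n = 2 each).

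**Figure D1:**
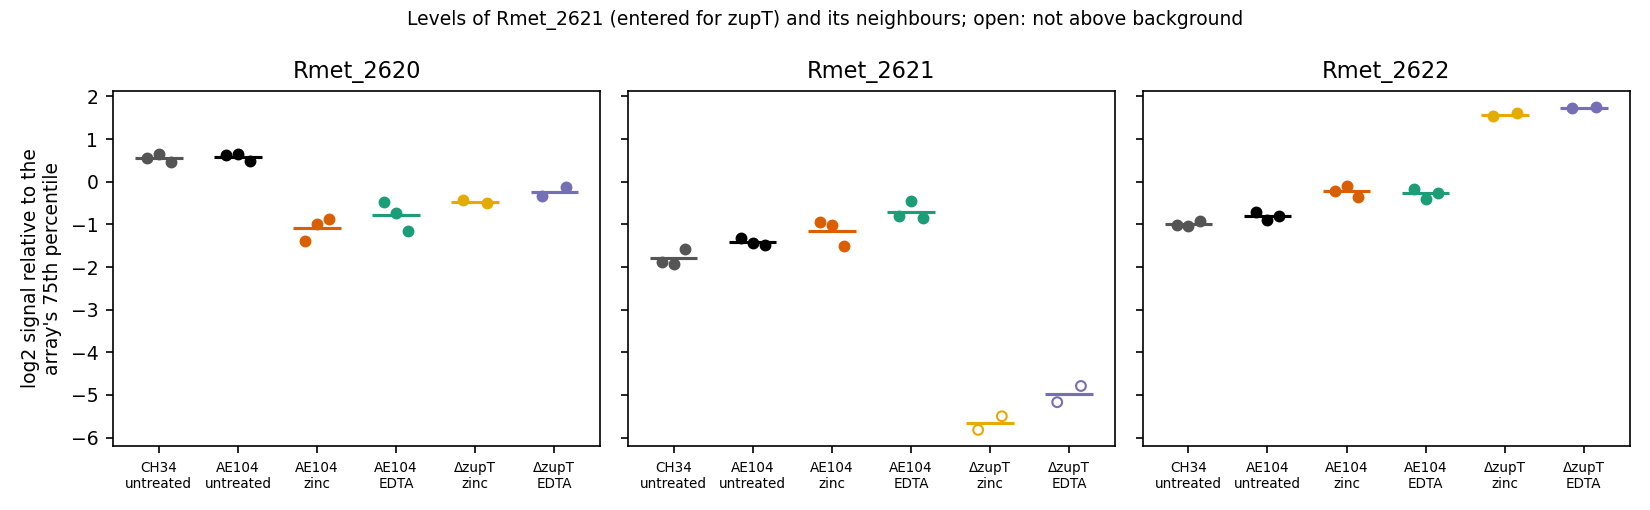
Log2 signal of Rmet_2620, Rmet_2621 and Rmet_2622 relative to the 75th percentile of each array, 1 point per array with group means as lines and open points for signals not well above background. Rmet_2621 lies near -1.15 and -0.71 in treated AE104 and at -5.66 and -4.98 in the deletion strain, where all 4 points are open.

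CH34 and AE104 were compared without treatment to see which transcripts accompany the 2 plasmids. Of 5434 measured features, 448 changed, 428 of them higher in CH34 and 20 lower. The plasmid block held the 417 features with probe numbers before dnaA, with locus tags from 5942 to 6344 and some longer tags. Of these, 323 were measured, 266 were higher in CH34, 1 was lower and 56 did not pass. Adjusted over the list alone, 274 members changed, and the block as a whole was higher by camera with an estimated correlation too (adjusted p = 0.000689, median log2 change 3.55). In this block, 237 features were well above background on every CH34 array and on no untreated AE104 array, with a median at-least fold of 5.1. There were also 60 block features well above background on every untreated AE104 array. Since AE104 and its deletion strain lack the plasmids, signals of block features there cannot be read as those of plasmid genes. Their source was not tested. Rmet_62630 of the block was at least 243-fold higher in CH34 (log2 change 10.21, SE 0.24, adjusted p = 4.17e-13).

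Outside the plasmid block, 162 features were higher in CH34 and 19 were lower. Only 2 of the 323 measured features with a symbol changed. The gene rbcL, for the large subunit of ribulose-1,5-bisphosphate carboxylase, was at least 16.4-fold higher (log2 change 4.12, SE 0.32, adjusted p = 7.41e-08, 3 arrays against 3). A copy of pgk, the gene of the glycolytic and Calvin cycle enzyme phosphoglycerate kinase, listed as pgk__2, was at least 6.2-fold higher (3.86, SE 0.26, adjusted p = 1.25e-08). Under normexp with quantile normalization, rbcL rose by 1.55 and pgk__2 by 0.67, short of the fold minimum, and with a common floor pgk__2 rose by 1.18. Rmet_4596 was at least 38.6-fold lower in CH34 (-5.46, SE 0.30, adjusted p = 1.36e-09) and Rmet_6002, the member of the plasmid block that fell, 9.21-fold lower (-3.20, SE 0.36, adjusted p = 4.59e-06); normexp gave -2.50 and -1.74. Of the 15 lists other than the plasmid block, none was called by camera. Flagella and motility came closest from above, with a median of 0.33 and an adjusted p of 0.0817, and the heme, cobalamin and cofactor list from below, with -0.24 and 0.0817.

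Neighbouring tags moved together, in runs that were chosen after the values were seen. A run of 20 features from Rmet_1508 on was higher in CH34 by a mean of 5.36 on the log2 scale, and a further run of 14 ended at Rmet_1547 with a mean of 6.68; the longest run in 1000 shuffled orders had 4 features. Of the 38 features between these ends, 38 were well above background on all arrays of CH34 and 9 on all arrays of untreated AE104. The count was 24 in AE104 with zinc, 22 in AE104 with EDTA, 37 in the deletion strain with zinc and 36 in the deletion strain with EDTA. The median log2 level of the region was -5.28 in untreated AE104, -0.15 in AE104 with zinc and -0.50 in AE104 with EDTA. In the deletion strain it was 2.76 with zinc and 2.00 with EDTA. CH34 and untreated AE104 lay on separate slides. A purely technical difference between slides would follow neither gene order nor replicon, so the 2 runs argue against that for their features. The plasmid block does too, with 266 of 323 measured features higher in CH34, against 162 outside it among 5434 measured in all. A difference between the samples other than strain also coincides with slide. It can move neighbours together, so the runs cannot speak against it, and the region differed between the AE104 groups as well. For single features elsewhere, slide and strain cannot be told apart. Within 1 slide, the region was also higher in the deletion strain than in AE104 with EDTA, in runs of 22 and 14 features with means of 3.03 and 3.07. Between CH34 and untreated AE104, 51 features changed when required to be above background in both groups, and 235 changed with a common floor.

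**Figure D2:**
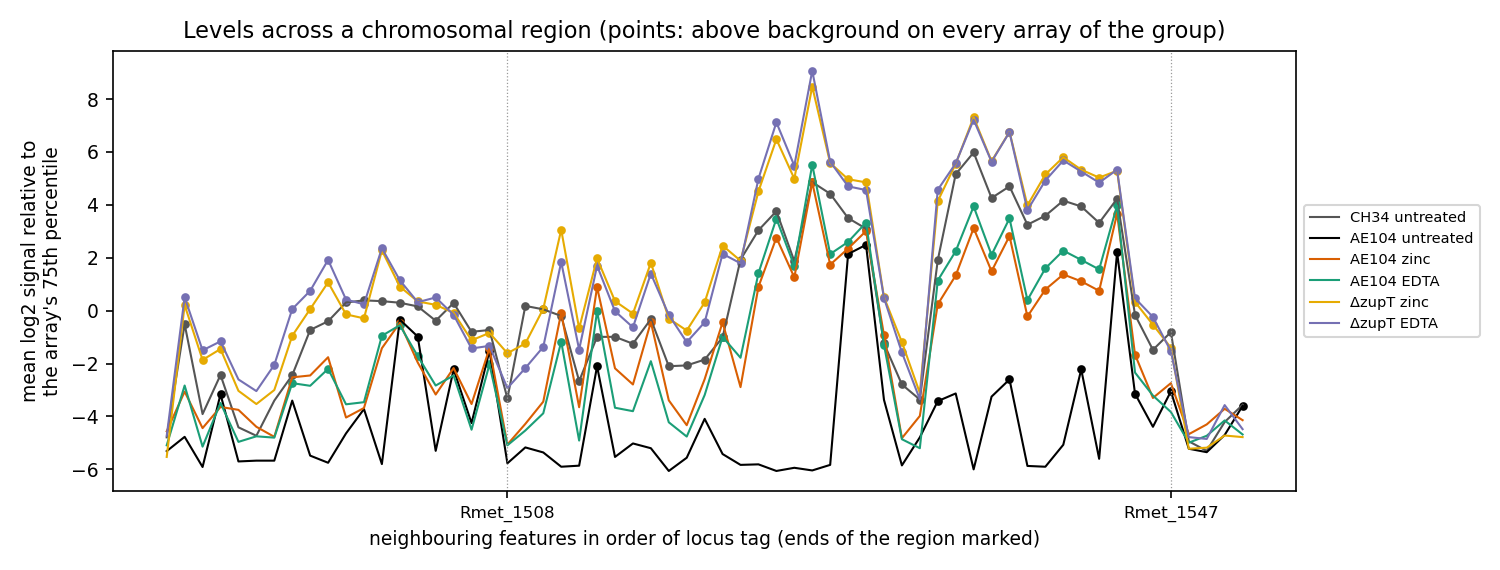
Mean log2 signal of neighbouring features, in order of locus tag, relative to the 75th percentile of each array, 1 line per group; points mark features well above background on every array of a group, and dotted lines mark the ends Rmet_1508 and Rmet_1547. Between these ends the line of untreated AE104 has a median of -5.28 and those of the deletion strain have medians of 2.76 with zinc and 2.00 with EDTA.

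AE104 grown with EDTA was compared with AE104 grown with zinc to see which transcripts differ between the 2 media. Of 4276 measured features, 344 were higher with EDTA and 170 lower, and 30 of the 304 measured features with a symbol changed. By adjusted p alone, without the fold minimum, the balance turned, with 620 higher and 780 lower. Genes of the flagellum rose as a group: 13 of 18 measured members of the flagella and motility list were higher with EDTA, 1 was lower and 4 did not pass, and adjusted over the list alone 14 were higher and 1 lower. The median log2 change was 1.29 (camera adjusted p = 1.87e-06; adjusted p = 0.296 with an estimated correlation). The rod protein gene flgB was 3.04-fold higher (log2 change 1.60, SE 0.21, adjusted p = 6.29e-05), the hook capping gene flgD 3.26-fold (1.70, SE 0.21, adjusted p = 3.62e-05) and motB, which encodes a stator protein of the motor, at least 2.84-fold (1.51, SE 0.22, adjusted p = 0.000129). The member that fell was fliF, for the membrane ring of the basal body, at 4.79-fold lower (-2.26, SE 0.37, adjusted p = 0.000371). Its rise with zinc against no treatment and its fall in the deletion strain with zinc, given below, rest on the same zinc arrays, which had a slide of their own. In the deletion strain, where both media shared a slide, no measured member of the list was called lower with EDTA. Normexp with quantile normalization and the authors' value table left flgB and fliF past the threshold and gave less than the fold minimum for flgD (0.68 and 0.75) and motB (0.62 and 0.68).

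Some genes of the citrate cycle fell with EDTA. In that list, 3 of 6 measured members were lower and 3 did not pass, adjusted over the list alone also 3, with a median of -0.84 (camera adjusted p = 0.00771; adjusted p = 0.257 with an estimated correlation). These were sdhA and sdhB, for subunits of succinate dehydrogenase, and gltA, for citrate synthase. The change was -1.62 for sdhA (SE 0.24, adjusted p = 0.000172, 3.07-fold lower), -1.16 for gltA (SE 0.19, adjusted p = 0.000359) and -1.07 for sdhB (SE 0.21, adjusted p = 0.00136). Both gltA and sdhB dropped out without AE104_zinc replicate 1 (-0.99 and -0.87), and sdhB also without AE104_EDTA replicate 2 (-0.97); normexp (-0.89 and -0.70) and the value table (-0.97 and -0.78) had the same effect on both. In contrast, purT, for a formyltransferase of purine synthesis, was 4.72-fold higher (2.24, SE 0.12, adjusted p = 2.3e-09) and kept its call under every alternative run. The largest rises were at Rmet_5374, at least 1280-fold (11.38, SE 0.55, adjusted p = 4.27e-10), and Rmet_5377, at least 953-fold (10.86, SE 0.24, adjusted p = 6e-14). Rmet_4596 was at least 173-fold lower (-8.72, SE 0.30, adjusted p = 8.88e-12) and Rmet_6002, placed in the plasmid block by probe number, at least 59.4-fold lower (-6.23, SE 0.36, adjusted p = 3.08e-09), with -5.35 and -3.80 under normexp. AE104 has no plasmids, so the signal of Rmet_6002 there cannot be taken as that of a plasmid gene.

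Ribosomal protein genes had a median change of -0.52 between EDTA and zinc in AE104 (camera adjusted p = 0.00217; adjusted p = 0.662 with an estimated correlation), with 4 of 47 lower and 0 higher, also adjusted over the list alone. None of the 4 held without AE104_zinc replicate 1: rplQ went from -1.09 to -0.81, rpsQ from -1.03 to -0.75, rplF from -1.01 to -0.66 and rpsR to -0.77. Without AE104_zinc replicate 3, in contrast, 14 of the 47 were lower, with a median of -0.77 (camera adjusted p = 2.9e-06). In the heme, cobalamin and cofactor list 1 of 21 measured members was lower (median -0.40, camera adjusted p = 0.00067; adjusted p = 0.245 with an estimated correlation). That was cobT, of cobalamin synthesis (-1.49, SE 0.30, adjusted p = 0.00189), which normexp put at -0.66 and the value table at -0.81. No member passed in the chaperone and protease list (6 measured, median 0.57, camera adjusted p = 0.029) or in the amino acid list (16 measured, median -0.38, camera adjusted p = 0.0211). In the DNA replication and repair list, 1 of 23 passed (median -0.26, camera adjusted p = 0.0248). The adjusted p values of these 3 lists with an estimated correlation were 0.245, 0.451 and 0.451. The zinc and EDTA arrays of AE104 lay on separate slides, so slide and medium cannot be told apart within this strain.

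AE104 with zinc was compared with untreated AE104 to see what added zinc changed. Of 5106 measured features, 895 were higher and 960 lower with zinc; 62.8% were higher without a filter and 60.9% with the stricter filter. In the flagella and motility list 15 of 20 members were lower, 1 was higher and 4 did not pass, and adjusted over the list alone 16 changed, with a median of -1.69 (camera adjusted p = 0.00428; adjusted p = 0.935 with an estimated correlation). The hook-filament junction gene flgL fell at least 7.41-fold (-3.11, SE 0.40, adjusted p = 6.82e-06), and fliF rose by 3.42 on the log2 scale (SE 0.37, adjusted p = 1.08e-06). For flgL, normexp gave -1.52 and the value table -1.25. In the value table the list's median was 0.22, against 1.08 for all measured features there, so the list lay above 0 and below the other features. Ribosomal protein genes were split: 15 of 47 were lower and 2 higher, also 17 adjusted over the list alone, and a median of -0.73, while 47 of 68 features with tags of the RNA series were lower and 2 higher (median -1.92). The gene rpmI fell 16.6-fold (-4.06, SE 0.18, adjusted p = 8.39e-11) and rpsI 11.9-fold (-3.58, SE 0.17, adjusted p = 1.51e-10), whereas rpsA rose 7.02-fold (2.81, SE 0.21, adjusted p = 2.42e-08). The chaperonin genes groES and groEL fell 6.13-fold (-2.62, SE 0.16, adjusted p = 2.27e-09) and 5.37-fold (-2.43, SE 0.12, adjusted p = 2.36e-10). The genes rpmI, rpsI, rpsA, groES and groEL moved the same way with EDTA against no treatment, so their changes were not particular to zinc.

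With groES, groEL and clpX, 3 of 6 measured members of the chaperone and protease list were lower with zinc than without treatment, also adjusted over the list alone, and none was higher, at a median of -0.93. For clpX, the ATPase subunit of a protease, the change of -1.17 (SE 0.16, adjusted p = 1.82e-05) was -0.63 under normexp and 0.02 in the value table, where the median change of all features was 1.22, so that clpX still lay below most of them. The camera calls of the ribosomal (adjusted p = 0.0261) and chaperone (adjusted p = 0.0307) lists were lost with an estimated correlation (adjusted p = 0.935 and adjusted p = 0.286) and without AE104_zinc replicate 3 (adjusted p = 0.343 and adjusted p = 0.0765). Without that array the ribosomal median was -0.42, with 11 members lower and 5 higher, and the chaperone median -0.83. Genes that rose included valS0 and pheT, which carry the names of valyl- and phenylalanyl-tRNA synthetases, at 9.79-fold (3.29, SE 0.21, adjusted p = 4.24e-09) and 6.11-fold (2.61, SE 0.20, adjusted p = 2.31e-08). The transcription termination factor gene rho rose 4.35-fold (2.12, SE 0.19, adjusted p = 1.27e-07), the elongation factor gene tsf 3.38-fold (1.76, SE 0.20, adjusted p = 1.85e-06) and pyrB, of pyrimidine synthesis, 7.08-fold (2.82, SE 0.23, adjusted p = 6.78e-08; 1.39 under normexp). The rise of pyrB was shared with EDTA against no treatment. In the phosphate uptake list 1 of 3 measured members rose and none fell, and the list was not called. Its riser, pstA, had a change of 2.55 (SE 0.41, adjusted p = 7.41e-05), with 0.67 under normexp and 1.35 with a common floor.

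Among features without a symbol, Rmet_1526 was at least 415-fold higher with zinc than without treatment (log2 change 10.89, SE 0.37) and Rmet_1535 at least 125-fold (9.13, SE 0.37); normexp gave 5.83 and 4.06 and a common floor 7.24 and 5.52. Both lie between Rmet_1508 and Rmet_1547, where untreated AE104 stood apart from all other groups: Rmet_1526 had a mean level of -6.04 there, against 4.86 in untreated CH34, 4.85 in AE104 with zinc and 5.52 in AE104 with EDTA, so the rise was not particular to zinc. Rmet_R0074 was 270-fold lower (-8.08, SE 0.32, adjusted p = 3.84e-11) and Rmet_6310, a tag of the plasmid block measured in the plasmid-free strain, at least 68.6-fold lower (-7.43, SE 0.50, adjusted p = 7.8e-09; -4.22 under normexp and -4.49 in the value table). Untreated and treated arrays were scanned on different days and lay on different slides, so scan day, slide and medium cannot be told apart in either comparison with untreated AE104. The main axis of variation across all arrays, the first principal component, held 51.1% of the variance. On it untreated arrays of both strains lay at -76.4 to -53.5 and treated arrays at 16.3 to 55.8. With the value table, 92.1% of the changed features were higher with zinc, against 48.2% in the scanner data, and the median change of all features was 1.22 against 0.06. In both comparisons with untreated AE104, that table kept a higher negative control level on the treated arrays, which raises dim features there. How much of the shift this accounts for was not tested.

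EDTA was set against untreated AE104 to see what depletion of metals changed. Of 5196 measured features, 957 were higher and 1110 lower. Ribosomal protein genes fell as a group, with 21 of 47 lower, 1 higher and 25 that did not pass, adjusted over the list alone also 22, and a median of -0.93 (camera adjusted p = 0.0001; adjusted p = 0.811 with an estimated correlation). The gene rpsI fell 17.1-fold (-4.10, SE 0.17, adjusted p = 2.08e-11), rpmI 17.0-fold (-4.09, SE 0.18, adjusted p = 3.96e-11) and rpsU 8.06-fold (-3.01, SE 0.30, adjusted p = 3.77e-07), and rpsA rose 4.64-fold (2.21, SE 0.21, adjusted p = 2.76e-07). In the same comparison 50 of 68 features with tags of the RNA series were lower and 4 higher, at a median of -2.07, so the fall was not confined to ribosomal protein genes. In the citrate cycle list 3 of 6 members were lower, adjusted over the list alone also 3, and the list as a whole was not called (median -1.06, camera adjusted p = 0.101). Citrate synthase gene gltA fell 3.63-fold (-1.86, SE 0.19, adjusted p = 4.47e-07) and sdhA 2.82-fold (SE of the log2 change 0.24, adjusted p = 6.14e-05). In the chaperone and protease list 3 of 6 were lower, adjusted over the list alone also 3, without a list call (median -0.93, camera adjusted p = 0.185); groES fell 3.31-fold (-1.73, SE 0.16, adjusted p = 1.67e-07) and groEL 2.90-fold (-1.54, SE 0.12, adjusted p = 2.31e-08).

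Flagellar genes went both ways with EDTA against no treatment, with 3 of 20 higher, 4 lower, 7 changed adjusted over the list alone, a median of -0.50 and no list call (camera adjusted p = 0.599); in the value table their median was 0.65. Examples were flgK, for a hook-filament junction protein, at -2.19 (SE 0.34, adjusted p = 4.65e-05) and flgF, for a rod protein, at 1.32 (SE 0.20, adjusted p = 4.23e-05). Normexp gave -0.86 for flgK and 1.00 for flgF, and the value table -0.34 for flgK. The threonyl-tRNA synthetase gene thrS rose 6.15-fold (2.62, SE 0.26, adjusted p = 3.95e-07) and pyrB 5.35-fold (2.42, SE 0.23, adjusted p = 2.98e-07; 1.11 under normexp). The putA1 feature, named for an enzyme of proline degradation, fell at least 13.3-fold (-3.92, SE 0.37, adjusted p = 2.37e-07; -1.81 under normexp). Rmet_5374 was at least 4360-fold higher (13.26, SE 0.55, adjusted p = 2.45e-11) and Rmet_5377 at least 1860-fold (12.82, SE 0.24; 7.92 under normexp). Rmet_1991 was 170-fold lower (-7.41, SE 0.13, adjusted p = 2.53e-15) and Rmet_R0074 146-fold lower (-7.19, SE 0.32, adjusted p = 6.68e-11). With the value table, 91.3% of the changed features were higher, and the median change of all features was 1.16, against 46.3% and -0.08 in the scanner data; under normexp 60.1% were higher.

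The effect of the zupT deletion was taken from the deletion strain against AE104 in the same medium. With zinc, 189 of 4718 measured features were higher in the deletion strain and 186 lower, a balance that processing moved both ways (63.4% higher after median centring, 24.7% without a filter). The carbon fixation gene rbcL was at least 5.53-fold higher (3.39, SE 0.36, adjusted p = 2.17e-05, 2 arrays against 3) and pgk__2 4.99-fold higher (2.32, SE 0.29, adjusted p = 8.1e-05), with 1.14 and 1.19 under normexp and 1.29 and 1.35 in the value table. The region from Rmet_1508 to Rmet_1547 was raised as well, in runs of 23 features (mean 3.04) and 13 features (mean 3.71), and a run of 11 that held rbcL had a mean of 2.68; shuffled orders gave at most 4. Among the fallen, fliF was 4.46-fold lower (-2.16, SE 0.41, adjusted p = 0.00259) and valS0 2.27-fold lower (-1.18, SE 0.24, adjusted p = 0.00339), both short of the threshold when only the 2 groups entered the fit (adjusted p = 0.128 and adjusted p = 0.233). Rmet_5112 was at least 8.72-fold lower (-4.13, SE 0.37, adjusted p = 7.17e-06; -0.98 under normexp, -1.63 in the value table). With only these groups in the fit, 103 features changed in place of 375. The 2 strains lay on separate slides with zinc, so slide and deletion cannot be told apart there.

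Few members of any gene list passed between the deletion strain and AE104 with zinc. Ribosomal protein genes had 1 of 47 higher, 1 lower and a median of 0.40, flagella and motility 0 of 13 higher, 1 lower and -0.40, chaperones and proteases 1 of 6 higher and 0.49, amino acid biosynthesis 0 of 18 and 0.64, and protein secretion 1 of 8 higher and 0.41. Adjusted over the list alone, 2, 1, 1, 0 and 1 members changed. Their camera adjusted p values of 0.0272, 0.0135, 0.016, 0.0135 and 0.0135 were lost with an estimated correlation, as adjusted p = 0.825, 0.757, 0.226, 0.618 and 0.507. They were also lost without AE104_zinc replicate 3, as adjusted p = 0.975, 0.241, 0.0687, 0.0727 and 0.101. The medians were then 0.17 for ribosomal and -0.20 for flagellar genes, and moved less for the other lists, to 0.48, 0.52 and 0.34.

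With EDTA, where both strains shared 1 slide, 123 of 4360 measured features were higher in the deletion strain and 288 lower. The gene rbcL was at least 8.44-fold higher (3.70, SE 0.36, adjusted p = 7.01e-06, 2 arrays against 3) and pgk__2 at least 6.92-fold higher (2.91, SE 0.29, adjusted p = 8.41e-06), with 1.30 and 1.17 under normexp and 1.42 and 1.25 in the value table. Flagellar genes were lower, with 5 of 18 measured members past the threshold, 0 higher, 7 lower adjusted over the list alone and a median of -0.98 (camera adjusted p = 7.82e-06; adjusted p = 0.623 with an estimated correlation). Of these, flgH, for the outer membrane ring, was at least 3.03-fold lower (-1.64, SE 0.39, adjusted p = 0.00952), but fell short without dzupT_EDTA replicate 1 (-1.33, adjusted p = 0.113), under normexp (-0.36) and in the value table (-0.58). The export gate gene fliP (-1.35, SE 0.34, adjusted p = 0.0138) fell short without AE104_EDTA replicate 3 (-1.12) and without dzupT_EDTA replicate 2 (-1.13), and under quantile normalization (-1.15), normexp (-0.25), the value table (-0.49) and a common floor (-0.67). The rdgC gene, for a protein that binds DNA, was 2.93-fold lower (-1.55, SE 0.21, adjusted p = 9.2e-05) under every alternative run. Rmet_1098 was 85.2-fold higher (6.41, SE 0.51, adjusted p = 1.05e-06) and Rmet_4645 at least 32.3-fold lower (-5.07, SE 0.37, adjusted p = 6.07e-07; -2.58 under normexp, -2.99 in the value table).

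Ribosomal protein genes had 2 of 47 lower and 0 higher in the deletion strain with EDTA, adjusted over the list alone also 2, with a median of -0.33 (camera adjusted p = 0.00547; adjusted p = 0.966 with an estimated correlation). Of these, rplN was 2.84-fold lower (-1.51, SE 0.32, adjusted p = 0.00466) and just missed the threshold without dzupT_EDTA replicate 1 (-1.39, adjusted p = 0.0525). The chaperone and protease list had a median of 0.46 with 0 of 6 past the threshold (camera adjusted p = 0.012; adjusted p = 0.166 with an estimated correlation). The effects of the deletion in the 2 media, which share no arrays, correlated across 4159 features with r = 0.64 and rho = 0.40, where features are not independent replicates. Higher in both media were 63 features against 3.8 for independent lists. Most of them lay in 1 stretch from Rmet_1496 to Rmet_1547, much of which was also higher in CH34 than in untreated AE104. It held runs of 23, 13 and 11 risers with zinc and of 22, 14 and 12 with EDTA. Neighbours are not independent, so the 63 largely reflect that stretch. Lower in both were 95 against 9.6, and 3 lower with zinc were higher with EDTA.

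Within the deletion strain, EDTA was compared with zinc on arrays of 1 slide. Of 4777 measured features, 346 were higher with EDTA and 552 lower, and 95 of the 312 measured features with a symbol changed. Under normexp with quantile normalization the balance turned, with 176 higher and 146 lower. Ribosomal protein genes fell together: 33 of 47 were lower and 0 higher, adjusted over the list alone also 33, with a median of -1.27 (camera adjusted p = 2.05e-08; adjusted p = 0.384 with an estimated correlation). Of the 68 features with tags of the RNA series, 19 were lower and 5 higher (median -0.67). The small subunit gene rpsT was 3.79-fold lower (-1.92, SE 0.36, adjusted p = 0.000817, 2 arrays against 2), and the large subunit genes rplI 3.61-fold (-1.85, SE 0.32, adjusted p = 0.000507), rplX 3.46-fold (-1.79, SE 0.37, adjusted p = 0.00204) and rplN 3.32-fold (-1.73, SE 0.35, adjusted p = 0.00162). In the citrate cycle list 3 of 6 were lower, adjusted over the list alone also 3, with a median of -1.30 (camera adjusted p = 0.0235; adjusted p = 0.278 with an estimated correlation). The succinate dehydrogenase genes sdhA and sdhB changed by -2.70 (SE 0.29, adjusted p = 6.16e-06) and -2.09 (4.26-fold lower, SE 0.25, adjusted p = 1.73e-05; -1.37 under normexp), and gltA 3.58-fold (-1.84, SE 0.23, adjusted p = 2.4e-05).

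Further lists were lower with EDTA than with zinc in the deletion strain. In the amino acid list 8 of 18 members were lower, adjusted over the list alone also 8, with a median of -0.95 (camera adjusted p = 0.00313; adjusted p = 0.278 with an estimated correlation); leuD, of leucine synthesis, changed by -1.99 (SE 0.27, adjusted p = 5e-05; -0.99 under normexp, -1.29 in the value table). Of translation factors and RNA polymerase genes 8 of 22 were lower (median -0.65, camera adjusted p = 0.00313), of heme, cobalamin and cofactor genes 5 of 22 (-0.59, 0.00234) and of secretion genes 2 of 8 (-0.80, 0.00553), with adjusted p = 0.384, 0.278 and 0.278 with an estimated correlation. The last were secG and secE, subunits of the translocon, at -1.52 (SE 0.17, adjusted p = 1.15e-05) and -1.29 (SE 0.19, adjusted p = 0.000108). Nucleotide synthesis genes had 6 of 19 lower and 1, purT, higher (median -0.70, camera adjusted p = 0.0391; adjusted p = 0.278 with an estimated correlation). The aminoacyl-tRNA synthetases had 3 of 18 lower (-0.52, 0.0391) and the cell envelope genes 1 of 22 lower and 1 higher (-0.45, 0.045), with adjusted p = 0.387 and 0.384 with an estimated correlation. In AE104, translation factors, synthetases and cell envelope genes were not called between EDTA and zinc (camera adjusted p = 0.0745, 0.13 and 0.0703), but were called lower without AE104_zinc replicate 3 (camera adjusted p = 0.0113, 0.0321 and 0.0237).

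Flagella and motility rose in the deletion strain with EDTA against zinc for 3 of 13 measured members, with none lower, adjusted over the list alone also 3, and a median of 0.62 (camera adjusted p = 0.0157; adjusted p = 0.384 with an estimated correlation). These were motB (1.28, SE 0.27, adjusted p = 0.00186), flgD (1.06, SE 0.26, adjusted p = 0.00651) and flgB (1.02), none of which reached the fold minimum under normexp (0.41, 0.28 and 0.64) or in the value table (0.62, 0.52 and 0.64), and flgB also not without dzupT_zinc replicate 1 (0.94). The purine gene purT was 3.71-fold higher (1.89, SE 0.15, adjusted p = 1.9e-07) and groES 2.79-fold higher (1.48, SE 0.19, adjusted p = 3.87e-05), both under every alternative run. A run of 29 neighbours from Rmet_1092 to Rmet_1120 had a mean rise of 6.14, against at most 5 features in shuffled orders. Rmet_4596 was at least 137-fold lower (-8.98, SE 0.37, adjusted p = 7.24e-11) and Rmet_6002 at least 97.3-fold lower (-7.21, SE 0.44, adjusted p = 5.6e-09), with -5.15 and -4.25 under normexp.

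The change from zinc to EDTA in the deletion strain and in AE104, which share no arrays, correlated across 4134 features with r = 0.85 and rho = 0.67. Higher in both strains were 197 features, against 24.4 for independent lists, and lower in both were 114, against 18.3. As the plot of both strains shows, purT and flgD rose and sdhA fell in both, and Rmet_6002 lay at -6.23 in AE104 and -7.21 in the deletion strain.

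**Figure D3:**
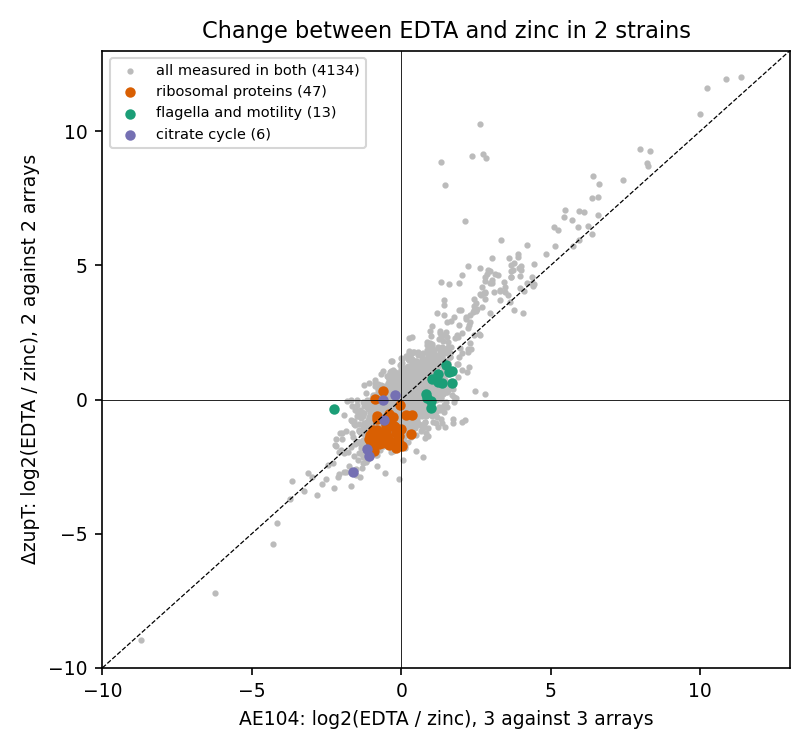
Log2 change between EDTA and zinc in AE104 (x axis, 3 arrays against 3) and in the deletion strain (y axis, 2 against 2), 1 point per feature measured in both, with 3 gene lists in colour and a dashed line of equal change. The median of the 47 ribosomal protein genes is -0.52 on the x axis and -1.27 on the y axis.

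The difference between the changes of the 2 strains was tested as an interaction. AE104 with zinc lay on another slide than the other groups of the interaction, so slide and strain cannot be told apart in it. Of 4919 measured features, 72 changed more upwards in the deletion strain and 127 more downwards. The ribosomal list was shifted downwards, with 5 of 47 members past the threshold, 0 upwards, 8 adjusted over the list alone and a median of -0.73 (camera adjusted p = 1.38e-06; adjusted p = 0.719 with an estimated correlation). Without AE104_zinc replicate 3 the median was -0.45, with 6 members past the threshold downwards and 2 upwards (camera adjusted p = 0.0141). Its member rpmA, at -1.57 (SE 0.32, adjusted p = 0.0156), missed the threshold without dzupT_zinc replicate 2 (-1.30, adjusted p = 0.0727), without dzupT_EDTA replicate 2 (-1.49, adjusted p = 0.062), after median centring (adjusted p = 0.0887) and with only these 4 groups in the fit (adjusted p = 0.095). The nucleotide list had 4 of 19 past the threshold, all downwards, also adjusted over the list alone (median -0.35, camera adjusted p = 0.00773; adjusted p = 0.351 with an estimated correlation). Its largest was carB1, named for carbamoyl phosphate synthase (-1.91, SE 0.37, adjusted p = 0.0117), which missed the threshold without dzupT_zinc replicate 2 (-1.56, adjusted p = 0.0575), under normexp (-0.63), with a common floor (-1.24, adjusted p = 0.0659) and with only these groups in the fit (adjusted p = 0.0823). Secretion genes (0 of 8, median -0.47, camera adjusted p = 0.00567) and translation factors (1 of 22, -0.54, 0.0167) were shifted downwards too, with adjusted p = 0.351 and adjusted p = 0.719 with an estimated correlation; the latter list was not called without AE104_zinc replicate 3 (adjusted p = 0.271). Without that array the nucleotide median was -0.55, and flagella and motility, not called with it (camera adjusted p = 0.0634), were called downwards (camera adjusted p = 0.0142, median -0.78, 3 lower and 1 higher).

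A run of 12 neighbours from Rmet_1093 to Rmet_1104 rose more in the deletion strain than in AE104, by a mean of 4.42, against at most 3 features in shuffled orders. The count of 199 features in the interaction depended on single arrays. It was 407 without AE104_zinc replicate 3, 101 and 100 without AE104_EDTA replicate 1 or 3, 90 without dzupT_zinc replicate 2 and 94 without dzupT_EDTA replicate 2. It was 76 after median centring and 47 with only the 4 groups in the fit.

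**Figure D4:**
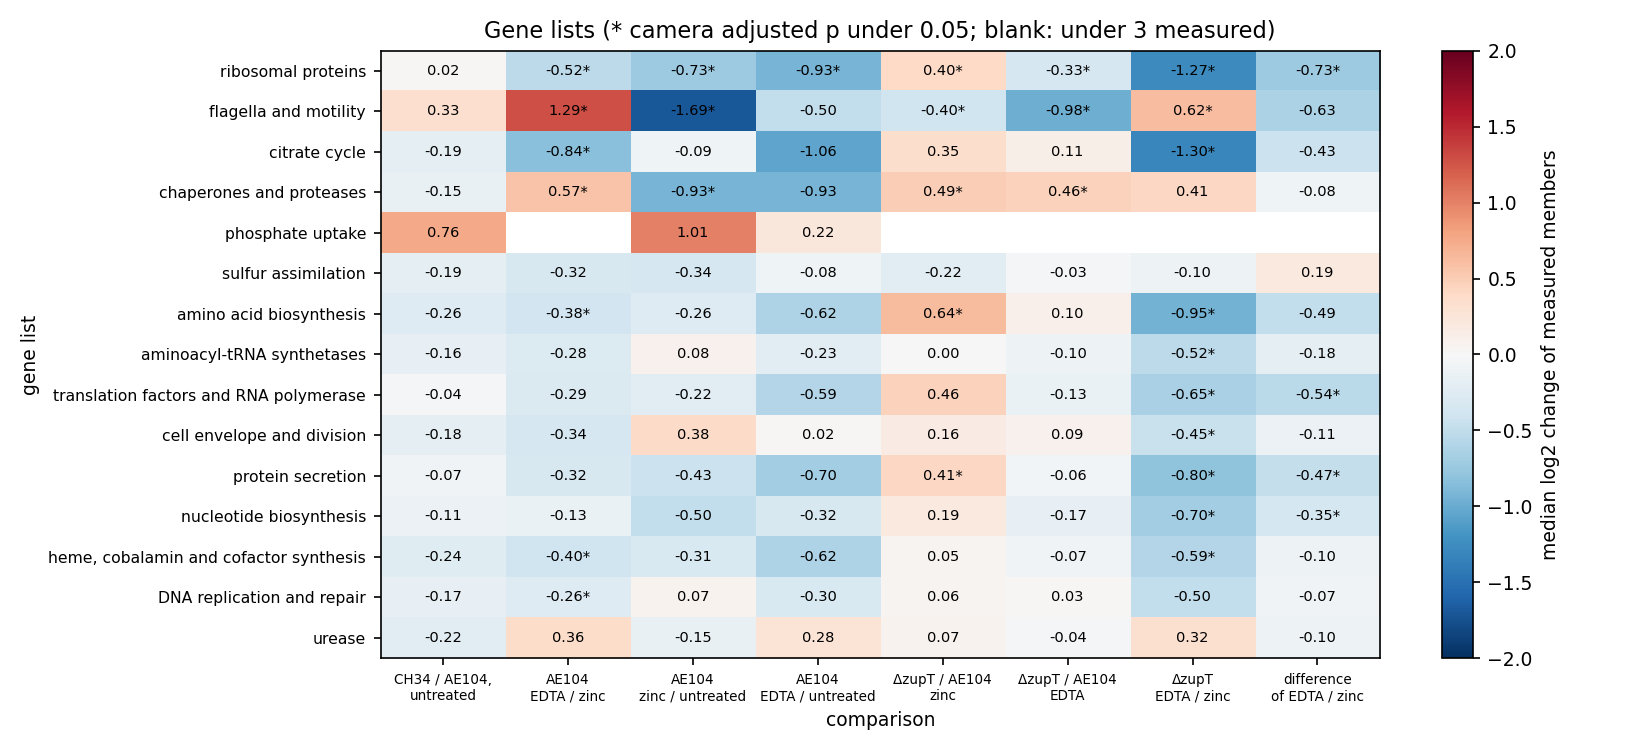
Median log2 change of the measured members of 15 gene lists (y axis) in the 8 comparisons (x axis), as a colour scale with the value in each cell; asterisks mark a camera adjusted p under 0.05 and blank cells lists with under 3 measured members. The ribosomal list runs from -1.27 for EDTA against zinc in the deletion strain to 0.40 for the deletion against AE104 with zinc, and the lists for sulfur assimilation, urease and phosphate uptake bear no asterisk.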

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

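The results below drew attention because they differ between the groups or come from parts of the files that the comparisons leave aside; apart from the splits of the arrays and the test of a background offset, the tests of explanations were chosen after the results were seen. The EDTA-over-zinc change differed between the deletion strain and AE104 for 199 features. The longest run of neighbours with the larger rise in the deletion strain had 12 features. Intergenic probes, which enter none of the gene comparisons, showed 40 of 50 features of pMOL28 and 86 of 109 of pMOL30 higher in CH34 than in untreated AE104. On AE104_zinc replicate 3, 56.2% of control spots were well above background, against 33.2% to 38.1% on the other arrays. Its median local background was 24.8, against 25.5 and 24.4 on the other zinc arrays of AE104, and its negative controls minus local background were 45.0, against 43.0 and 41.7, so the background was not raised with the spots. The cause was not tested.

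The change between EDTA and zinc in AE104 might come from the separate slides, from 1 aberrant zinc array or from the medium. Of the 467 features that changed there and were also measured in the deletion strain, where both media shared a slide, 435, or 93.1%, moved in the same direction, against 72.5% of the other 3667. That argues against the slides as the main source, and the same 93.1% is consistent with growth in the 2 media. Without the aberrant array the count rose from 514 to 635, which argues against that array as its source. What stays open is which part of the change comes from zinc and which from other metals bound by EDTA, since no sample separates them.

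For the large counts between treated and untreated AE104, a background offset of the arrays of the first scan day, a probe-specific difference between array runs, or the run or harvest day as a whole could be the cause. An offset would act most on dim features. With the measured features in 4 bins of brightness, 46.8% of the brightest bin changed with zinc and 22.7% of the dimmest (49.5% and 29.7% with EDTA). That argues against an offset as the source of the changes in the brightest bin. The bins left out features not measured in the comparison, so an offset among dim features stays open. For probe pairs of 1 gene that lie apart, the median difference between the changes of the 2 probes was 0.43 with zinc and 0.34 with EDTA, against 0.15 within a slide, and it was the larger in 48 of 61 genes (exact binomial p = 7.67e-06) and in 47 of 63 (exact binomial p = 0.000117). Earlier forms of that test used the share of changed genes with both probes moved: 99.3% and 99.1% against 99.8% for all pairs, most of which overlap, and 94.7% and 81.8% against 100.0% for pairs that lie apart. Between CH34 and untreated AE104, scanned on the same day, the difference between probes was larger than within a slide in 25 of 61 genes (exact binomial p = 0.2). The median differences with zinc and EDTA lay between the limits set for and against a probe-specific difference, so that test does not decide. The effect of the day stays open as well, because 0 groups were scanned on both days.

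The chromosomal features higher in CH34 than in untreated AE104 could reflect the 2 slides, or a genome segment silent or missing in the untreated AE104 samples. With EDTA, on 1 slide, 65 of 79 of them, or 82.3%, were higher in the deletion strain than in AE104, against 55.0% of other features. That comparison holds neither CH34 nor untreated AE104, and most of the 50 called there lie in 1 stretch of neighbours, so it does not decide on the slides. A purely technical difference between slides has no link to gene order. The runs of 20, 14 and 11 neighbours higher in CH34, against at most 4 in shuffled orders, therefore argue against that for those features. They cannot speak against a difference between the samples other than strain, which coincides with slide and can move neighbours together. For the other features the effect of the slides stays open. All 6 arrays were scanned on the same day. Of the 162, 114, or 70.4%, lay below background on every untreated AE104 array, but that share decides nothing, because the features were selected for low values there. Between Rmet_1508 and Rmet_1547, 24 of 38 features were not above background on any untreated AE104 array and 9 were above it on all. Among the 9, Rmet_1528, Rmet_1529 and Rmet_1543 had mean levels of 2.14, 2.49 and 2.21, so the region was not silent throughout. Whether parts of it are silent or missing, and whether strains of separate history were used, stays open, because no DNA was measured in the files used here.

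The arrays were also split into groups in all ways for the 4 comparisons of 3 arrays with 3. The real split gave the highest count in each, 1 of 10 splits, with 448 against 0 for CH34, 514 against 1 for EDTA against zinc in AE104, 1855 against 0 for zinc against no treatment and 2067 against 0 for EDTA against no treatment. With 10 splits no share under 0.05 can be reached.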

How the results depend on the processing

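Of 199 alternative counts, 162 lay within 1.5 times the reported one; among the named genes 4049 values were recomputed, of which 3680 kept their call, 368 were weaker, 0 stronger and 1 reversed. The last was clpX between AE104 with zinc and untreated AE104, at 0.02 in the value table (adjusted p = 0.861), where the median change of all features was 1.22, so its sign follows the scaling. Smaller folds of dim features follow in part from the settings. Normexp added an offset of 50, which shrinks such folds. Median processed signals per array ran from 16.97 to 61.29. Above a low cut, the value table followed the mean minus local background. That signal kept the negative control level of 35.9 to 45 on arrays of the first scan day. Between those arrays that level shrinks the folds of dim features too. On arrays of the second scan day, all untreated, the level was 3.49 to 4.86. Against those arrays it raises dim features on treated arrays in the value table. How much of any shift this accounts for was not tested, nor were other causes. The restriction to measured features, the common floor and the counting of all kept features were chosen after results were seen. A block for slide could not be run in 6 comparisons, nor one for scan day in any, nor the distance rule in SD units for the interaction.

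Counts that moved are given in the order CH34, EDTA against zinc in AE104, zinc and EDTA against untreated AE104, deletion with zinc, deletion with EDTA, EDTA against zinc in the deletion strain, interaction. Normexp with quantile normalization gave 150, 175, 679, 742, 95, 122, 322 and 69. The stricter filter gave 51, 307, 1218, 1364, 247 and 239 for the first 6. The value table gave 198 for EDTA against zinc in AE104 and 128, 149, 420 and 97 for the last 4. Adjusted p alone gave 1400, 3179, 3420, 991, 758 and 1675 for the second to the seventh. The deletion with zinc had 780 without a filter, 605 with all kept features counted and 103 with only its groups in the fit. The interaction had 47 with only its groups, 76 with median centring and 42 at an adjusted p under 0.01. A common floor gave 235 for CH34. The share higher for the deletion with zinc, 50.4%, was 60.6% under quantile normalization, 63.4% with median centring, 65.0% with only its groups, 39.3% with the stricter filter, 31.6% with all kept features, 24.7% without a filter and 47.0% to 49.3% in 5 others. The balance also turned for EDTA against zinc in AE104 by adjusted p alone (66.9% to 44.3%), for zinc against no treatment without a filter (48.2% to 62.8%), with the stricter filter (60.9%), all kept features (56.7%), normexp (56.0%), a common floor (51.6%), the value table (92.1%) and without AE104_zinc replicate 1 (50.7%). For EDTA against no treatment it turned under normexp (46.3% to 60.1%), with the stricter filter (53.5%), a common floor (50.6%), no filter (50.5%) and the value table (91.3%). So it did for EDTA against zinc in the deletion strain under normexp (38.5% to 54.7%) and for the interaction with only its groups (36.2% to 53.2%). Of list calls, 34 in the reported form, 1 was left with an estimated correlation and 52 came from fry, 27 of them shared. The correlation of the deletion effect in the 2 media was 0.80 over features changed in at least 1.

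Leaving out 1 array gave 434 to 469 features for CH34, 452 to 635 for EDTA against zinc in AE104, 1833 to 2105 for zinc against no treatment, 2033 to 2093 for EDTA against no treatment, 253 to 559 for the deletion with zinc, 293 to 437 with EDTA, 705 to 975 for EDTA against zinc in the deletion strain and 90 to 407 for the interaction; the correlation of the deletion effects ran from 0.57 to 0.65. For the deletion with zinc, 559 was reached without AE104_zinc replicate 3. A group left with 1 array was assumed to vary like the others.

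With a block for replicate number, although the numbers showed no pairing across groups, the counts in the same order were 452, 514, 1853, 2072, 390, 427, 884 and 170.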

Other observations

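Beyond the protein genes, 68 features bore tags of the RNA series. In AE104, 47 of them were lower with zinc than without treatment and 2 higher (median log2 change -1.92), and with EDTA 50 were lower and 4 higher (median -2.07). Between CH34 and untreated AE104 0 changed. Between EDTA and zinc 4 were lower and 3 higher in AE104, and in the deletion strain 19 were lower and 5 higher (median -0.67). The signal recognition particle RNA gene ffs fell 49.7-fold with zinc (-5.63, SE 0.16, adjusted p = 1.39e-12) and 39.0-fold with EDTA (-5.28, SE 0.16, adjusted p = 1.07e-12). The ribonuclease P RNA gene rnpB fell 9.08-fold (-3.18, SE 0.27, adjusted p = 7.71e-08) and 9.40-fold (-3.23, SE 0.27, adjusted p = 5.39e-08). Small RNAs are kept or lost by purification columns to varying degrees, and the treated and untreated samples differ in scan day.

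Intergenic features changed in every comparison: 198 of 2498 between CH34 and AE104, 181 of 1876 between EDTA and zinc in AE104, 1042 of 2365 with zinc and 1131 of 2411 with EDTA against no treatment, 216 of 2101 and 200 of 1935 between the deletion strain and AE104 with zinc and EDTA, 328 of 2121 between EDTA and zinc in the deletion strain and 57 of 2192 for the interaction. On pMOL28 the median log2 change between CH34 and AE104 was 4.18 and on pMOL30 3.26.

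A separate stretch of 11 features from Rmet_1288 to Rmet_1298, chosen after the values were seen, was well above background on all arrays of CH34 and on all arrays of 0 other groups. Its median log2 level was -0.53 in CH34, -5.75 in untreated AE104, -4.25 in AE104 with zinc, -5.01 in AE104 with EDTA, and -5.60 and -4.71 in the deletion strain. In the deletion strain with EDTA against zinc, a run of 17 features that held rplC and rplR fell by a mean of 1.38 on the log2 scale.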
